A study of Mus musculus with 6 samples.

How the data were processed

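Total RNA of mouse retina at postnatal day 21 was hybridised to Affymetrix 3′ expression arrays after a single amplification round with an oligo dT primer and biotin labelling, per the labels' protocols. The retinas were dissected into a preservative and 2 were pooled for each sample. Groups and replicate numbers were taken from the sample titles, with 3 arrays labelled wildtype and 3 labelled knockout. The labels do not say whether samples came from separate animals beyond the pools, so p-values measure the spread between these samples.

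The deposited values are intensities, 1 per probe set and array on a linear scale, that the authors made with software named as GCOS 1.4 and MAS5 in the submitters' processing notes. The role and order of these tools are not given in the sources used here. The table held 45101 probe sets, of which 64 Affymetrix controls were left out. The mean of each array after trimming 2% of probe sets at either end was close to 500 in replicates 1 and 2 of both groups and close to 150 in replicate 3 of both groups, so the deposited table is not on a single scale. These 2 sets of arrays also differed in more than scale. Correlations of log2 values, which a scale factor does not change, were 0.953 to 0.978 within a set and 0.799 to 0.864 between sets. On log2 values of the kept probe sets, the first principal component held 89.6% of the variance and separated these 2 sets of arrays, and the second held 5.44% and separated the groups mainly within the arrays scaled near 500 (loadings of -0.54 and -0.46 for wildtype, 0.47 and 0.51 for labelled knockout), with -0.067 and 0.090 for the wildtype and labelled knockout arrays scaled near 150. The 3′ to 5′ signal ratio was 0.712 to 0.779 for Gapdh with no split by group. For Actb it was 1.83, 1.89 and 2.32 in wildtype and 1.82, 1.66 and 1.67 in labelled knockout replicates 1, 2 and 3, so it was higher in every wildtype array. Array data of this kind carry no read depth, and precision is limited by the number of arrays. The median signal was 114 to 135 in the arrays scaled near 500 and 57.3 to 61.5 in those scaled near 150.

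Signals were transformed to log2 with no further normalization. Probe sets were kept when their mean log2 signal over the 6 arrays was at or above the 40th percentile of the 45037 non-control probe sets, a geometric mean signal of 54.5, which left 27022. The probe sets of Esrrb were tested, as the design fixed, in a fit of all 45037 without this filter, and their results in the filtered fit stand beside these. Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. Names came from an annotation table of the platform, in which 34945 probe sets had 1 gene symbol, 932 several and 9160 none. Of the 609 probe sets called with the batch as a block, 66 had no single symbol and are not named. Each of 12536 genes was represented by its kept probe set with the highest mean. Gene order along chromosomes came from a reference gene table of GRCm38.p6, of which no coordinates are used.

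The design fixed before the data were examined compared the groups over all 6 arrays with no covariate, on the premise that all arrays shared a scale. The values do not meet that premise. The fit was therefore also run with the scaling batch as a block, an alternative chosen after the array means and before any gene's test were seen. Each batch holds both groups in equal numbers, so fold changes are the same in both fits and only their errors differ. The descriptions of genes and lists use the fit with the batch as a block, and the counts of the fit without it stand beside them.

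Replicate numbers were checked for pairing. The deviations of samples from their group means correlated at 0.57, 0.67 and 0.843 for the pairs numbered 1, 2 and 3, above 0.1 in each, so the numbers pair the samples by that rule. Crossed pairs of numbers 1 and 2 gave 0.607 and 0.627, and within the arrays scaled near 500 the correlation of the pair numbered 1 was 0.0153. Beyond the scaling batch, the numbers 1 and 2 therefore showed no pairing, and the pair numbered 3 is a batch by itself. A replicate block leaves 2 residual degrees of freedom, against 3 with the batch as a block. A call can be lost with it for that reason. Results with a replicate block are given where they change a call or a count.

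Gene lists (33, fixed before the data were examined) were tested with camera on the representative probe sets with a preset inter-gene correlation of 0.01, again with the correlation estimated per list, and with fry. Of their 722 entries, 652 were matched to a gene on the array by symbol or unique synonym, before the filter on low signal. Fewer were tested, and the counts given as measured below are of members kept by the filter. With an estimated correlation 0 of the 33 lists passed under the batch block, and with fry 3 did (lens, fatty acid oxidation and circadian clock). Genes were named by a rule fixed beforehand. It takes Esrrb, the 10 largest increases and decreases among called genes whose groups do not overlap (applied within each scaling batch, since the scales differ), for a fit with no calls the 5 smallest p per direction, up to 4 members with the smallest p per list described, and Crx, Nrl, Nr2e3, Esrra and Esrrg. All 345 called genes had groups that did not overlap within either batch and differed in the same direction in both, as had 35.3% of all genes tested, where chance gives 16.7%.

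The fits were tested on simulated data of 27022 probe sets, with 200 changed in the comparison of knockout with wildtype. These data were made from the real batch means and from the residual spread as moderated by the fit with the batch as a block. With the batch as a block, 61 of 100 probe sets changed by a log2 of 1 and 92 of 100 changed by a log2 of 2 were recovered, with 15 false calls. With a replicate block these were 59 and 91, with 21 false calls, and with no block none was recovered. A rod list shifted in simulated data was called, and none of the 32 other lists was. The simulated noise was drawn independently for each probe set, so it does not check the list test where genes are correlated.

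Alternatives comprised the filter, an offset of 16, a floor at the 20th percentile, quantile normalization, median centring, no variance trend, array weights, probe sets with the suffixes _x_at and _s_at left out, a fold of at least 1.5, the mean of a gene's probe sets, a replicate block and each array left out, all planned, and the scaling batch as a block, its combination with the others and the arrays scaled near 500 alone, which were added after the data were seen.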

Results

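RNA from mouse retina was measured at postnatal day 21 on 6 short-oligonucleotide expression arrays. Of these, 3 were labelled wildtype, of C57Bl/6 background, and 3 were labelled knockout for ERRβ, the orphan nuclear receptor encoded by Esrrb, of mixed C57Bl/6 and Sv129 background. Each RNA came from 2 pooled retinas, and the labels give the sex of every sample as mixed. The single comparison of the design, knockout against wildtype, asks which retinal transcripts differ in level when ERRβ, a receptor studied for its part in keeping rod photoreceptors alive, is targeted. Genotype and strain background differ together, so every difference below is one between both. The values were intensities on which each array had been scaled as a whole, to a trimmed mean near 500 for replicates 1 and 2 of each group and near 150 for replicate 3 of each group. Log2 fold changes (labelled knockout minus wildtype) are means over the 3 arrays per group with a standard error (SE, n = 3 per group) from a limma fit in which this scaling batch is a block, and values within the 4 arrays scaled near 500 and within the 2 scaled near 150 are given for the lists that passed, for some of the genes named and, in a plot, for the 20 most changed genes. The number of arrays, 3 per group, limits the precision.

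Esrrb itself was not lower in the arrays labelled knockout. Its brightest probe set read 2951 and 2934 in the wildtype and 3435 and 4012 in the labelled knockout arrays scaled near 500, and 1771 against 2397 in those scaled near 150, a log2 fold change of 0.37 ± 0.083 (higher in both batches; adjusted p = 0.0852 in limma with the batch as a block). For Esrrb the design fixed a fit of all 45037 probe sets without the filter on low signal, which these errors and p come from. For a second probe set the change was 0.45 ± 0.11 (adjusted p = 0.0901), and for the third, whose probes can cross-hybridise, it was 0.19 ± 0.12 (adjusted p = 0.547), with 0.31 in the arrays scaled near 500 and -0.05 in those scaled near 150. In the filtered fit used for all other genes, adjusted p was 0.0529, 0.0626 and 0.439 for the same 3 probe sets, and none passed. That result lies at the threshold, and other settings of this fit called Esrrb higher. Exact two-sided permutation tests over the 6 arrays gave p = 0.4, 0.5 and 0.7 in the same order, where 0.1 is the smallest p that 3 against 3 allow. These permutations ignore the scaling batch, so the difference between the 2 sets of arrays enters their spread and they do not decide on Esrrb. Where the probe sets lie relative to the deleted part of the gene is not given in the sources used here, so their signal does not check the labels, and the arrays are called labelled knockout throughout.

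Lens genes showed the largest increases. Crygb and Crygd, which encode γ-crystallins of the lens fibre, were higher in the arrays labelled knockout, with log2 fold changes of 5.83 ± 0.16 (adjusted p = 3.79e-07) and 5.17 ± 0.19 (adjusted p = 3.01e-06). Crygb read 195 ± 61.7 in wildtype and 10041 ± 1078 in labelled knockout arrays scaled near 500 (SD, n = 2 each), and 38.2 against 2526 in those scaled near 150. All 10 genes with the largest increase belonged to the lens list. The others were the crystallin genes Crygf (4.52 ± 0.53), Cryga (4.39 ± 0.54), Crybb1 (4.13 ± 0.20), Cryba4 (3.85 ± 0.19), Cryba2 (3.68 ± 0.21) and Cryba1 (3.52 ± 0.36), together with Bfsp1 (3.98 ± 0.38), which encodes a beaded filament protein of lens fibres, and Mip (3.80 ± 0.26), the lens fibre water channel, with adjusted p from 1.16e-05 for Crybb1 to 0.00463 for Cryga. Several wildtype signals are low. In the arrays scaled near 500 and near 150 Cryga read 45.6 and 4.06 and Bfsp1 34.7 and 6.00. Crygb and Crygd read 38.2 and 42.7 in the wildtype array scaled near 150, whose median was 57.3. No detection limit is given, so the sizes of these changes are approximate. With 16 added to every signal Crygb had 5.58, Crygd 4.93, Cryga 3.60 and Bfsp1 3.06, and all 4 still passed. Of genes with wildtype signals above the array medians, Cryba1 had 4.29 and 2.00 and Crybb1 4.49 and 3.41 in the arrays scaled near 500 and near 150. Of 18 measured lens list members, 17 rose and none fell (18 rose when adjusted over the list alone). The median log2 fold change was 3.60, with 3.92 in the arrays scaled near 500 and 2.72 in those scaled near 150. The list passed camera (adjusted p = 6.52e-38), with adjusted p = 0.277 with an estimated correlation. The Actb ratio of 3′ to 5′ signal was 1.83 or more in each wildtype and 1.82 or less in each labelled knockout array, while that of Gapdh did not split by group. γ-crystallin genes are close paralogs, so a probe set of one may bind RNA of another.

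On the list of retinal pigment epithelium and choroid, 4 of 19 measured members rose and none fell (8 rose and 1 fell when adjusted over the list alone). They were the melanosome genes Tyrp1 (0.77 ± 0.091), Pmel (1.05 ± 0.13), Mlana (1.19 ± 0.16) and Dct (0.62 ± 0.097). The list's median was 0.37, and 0.33 and 0.63 within the arrays scaled near 500 and near 150 (camera adjusted p = 2.69e-05, and adjusted p = 0.387 with an estimated correlation).

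The 10 genes with the largest decrease came from several functions. Mef2c, a transcription factor of muscle, neurons and photoreceptors, fell 6.88-fold, with a log2 fold change of -2.78 ± 0.28 (adjusted p = 0.0017; -3.31 and -1.72 in the arrays scaled near 500 and near 150) and a decrease in each of its 5 kept probe sets. The stress-induced Hsp70 genes Hspa1b (-2.15 ± 0.12, adjusted p = 4.03e-05) and Hspa1a (-1.66 ± 0.21, adjusted p = 0.00549) fell, although these near-identical neighbours can share a probe's signal. Pdia5, a protein disulfide isomerase, fell by 2.01 ± 0.11 on the log2 scale (adjusted p = 1.91e-05), and the uncharacterised transcript A930003A15Rik changed by -2.20 ± 0.10 (adjusted p = 1.13e-05). Traf3ip3 (-2.91 ± 0.37), Abca13 (-3.22 ± 0.58), Ppara (-2.23 ± 0.48), the nuclear receptor that drives fatty acid oxidation genes, and Guca1a (-1.83 ± 0.15), which encodes a calcium sensor of photoreceptor guanylate cyclase, also fell. The values in the arrays scaled near 500 and near 150 were -3.36 and -1.99 for Traf3ip3, -4.35 and -0.96 for Abca13, -2.88 and -0.93 for Ppara, and -2.01 and -0.96 for Hspa1a. In labelled knockout arrays Traf3ip3 read 57.3 and 23.5 and Abca13 30.7 and 23.0 at the 2 scales, and Ppara read 87.9 near 500, all under the array medians, so these changes are approximate. With 16 added to every signal Traf3ip3 had -2.50 and Abca13 -3.17, and both still passed. A second kept probe set of Abca13 had -4.37 and did not pass (adjusted p = 0.0897). Among the probe sets that represent called genes, that of Prune2 had the largest decrease, -3.82 ± 0.80 (adjusted p = 0.0451). But this was -5.55 in the arrays scaled near 500 and -0.36 in those scaled near 150. The 2 other kept probe sets of Prune2 do not share this direction: 1 was called higher (0.55, adjusted p = 0.0238) and 1 did not pass (0.14), so no direction is given for the gene. In the arrays scaled near 500 alone another probe set represents Prune2 and its change is 0.62. With a replicate block Prune2, Abca13 and Ppara no longer passed (adjusted p = 0.0925, 0.0644 and 0.0713).

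**Figure D1:**
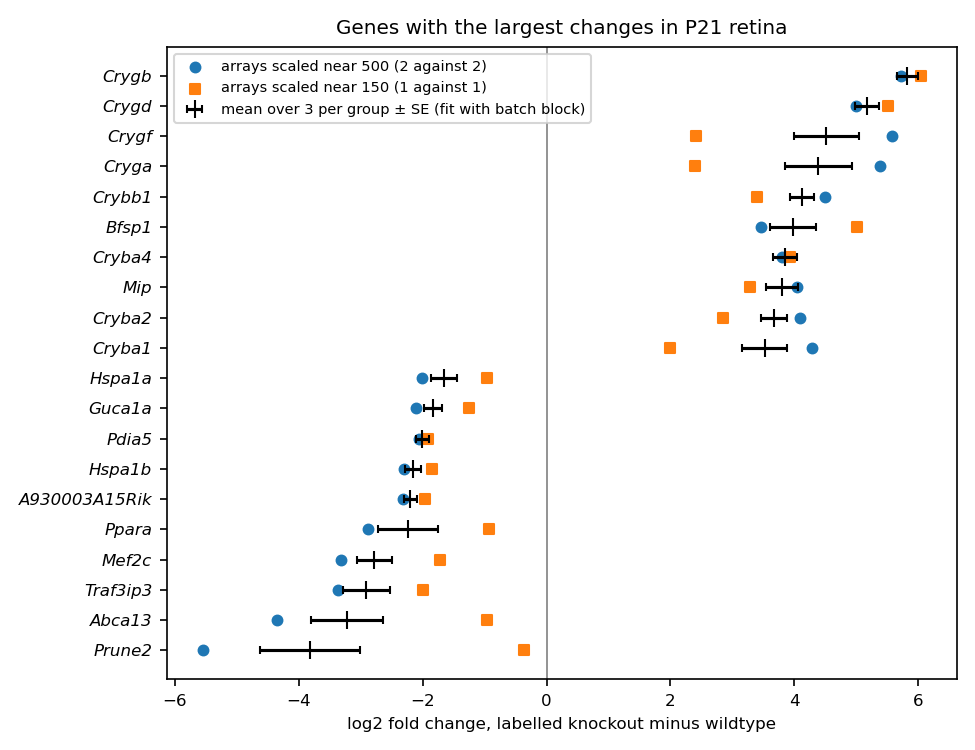
Log2 fold change (x axis, labelled knockout minus wildtype) of the 20 genes with the largest changes (y axis), as the mean over 3 arrays per group with its SE (black ticks and bars), within the 4 arrays scaled near 500 (blue circles) and within the 2 scaled near 150 (orange squares). All lie on the same side of 0 in both sets of arrays, and Prune2 has the widest gap, with -5.55 against -0.36. Values of genes with low signals, such as Cryga and Bfsp1, are approximate.

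Rod photoreceptor genes were lower on balance, with a spread between members and between the sets of arrays. Of 34 measured genes of rod phototransduction and the outer segment, 8 fell, 1 rose and 25 did not pass (14 fell and 1 rose when adjusted over the list alone). Guca1a fell most, from 21183 ± 677 to 4894 ± 104 in the arrays scaled near 500 (SD, n = 2 each) and from 2810 to 1176 in those scaled near 150. Aipl1, a chaperone of rod phosphodiesterase, changed by -0.73 ± 0.079 (adjusted p = 0.00225), Guca1b by -0.68 ± 0.086 (adjusted p = 0.00549) and Reep6 by -0.67 ± 0.094 (adjusted p = 0.0089). Guca1b and Guca1a are neighbours in the order of tested genes. The member that rose, singled out after its value was seen, was Cngb1, the β subunit of the rod cyclic nucleotide gated channel (0.34, adjusted p = 0.0428). With a replicate block 6 members fell and none rose, and Cngb1 did not pass (adjusted p = 0.105). The list's median was -0.31 (camera adjusted p = 1.36e-08, and adjusted p = 0.569 with an estimated correlation). This shift was -0.40 in the arrays scaled near 500, where 30 of 34 members were lower, and -0.01 in those scaled near 150, where 17 of 34 were lower, so it did not hold as a list shift in the second set. In the same arrays the lens list was higher by a median of 3.60 and the pigment cell list by 0.37. The 3′ to 5′ signal ratio of Actb, a sign of RNA quality, also moved with the groups, at 1.83, 1.89 and 2.32 in wildtype and 1.82, 1.66 and 1.67 in labelled knockout replicates 1, 2 and 3. That of Gapdh ran from 0.712 to 0.779 and did not split by group.

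Transcription factors that specify photoreceptors did not pass as a list (15 measured, median -0.15, camera adjusted p = 0.0573). Mef2c fell, and the other 14 members did not pass (2 rose and 6 fell when adjusted over the list alone). The rod factors Crx and Nrl had log2 fold changes of -0.19 ± 0.069 (adjusted p = 0.175; 0.05 for its second kept probe set) and -0.25 ± 0.068 (adjusted p = 0.0931). The related receptors Esrra and Esrrg had -0.15 ± 0.12 (adjusted p = 0.513) and -0.00 ± 0.091 (adjusted p = 0.991). Their second kept probe sets had -1.02 (adjusted p = 0.183) and 0.20 (adjusted p = 0.624). Nr2e3 was not analysed here, since no probe set carried that name in the annotation used. On the cone photoreceptor list Guca1a, which it shares with the rod list, fell, and the other 15 of 16 measured members did not pass (median -0.07, adjusted p = 0.492). Among 22 photoreceptor synapse genes, the calcium channel subunit gene Cacna2d4 (-0.46 ± 0.081) and the complexin gene Cplx4 (-0.46 ± 0.095) fell (1 rose and 4 fell when adjusted over the list alone). Neither passed with a replicate block (adjusted p = 0.0666 and 0.1). Both were lower in the arrays scaled near 500 and near 150 (-0.45 and -0.48 for Cacna2d4, -0.60 and -0.16 for Cplx4). In the fit of the arrays scaled near 500 alone another probe set, with 0.010, represents Cacna2d4. That list's median was -0.14, with -0.17 and -0.08 in the arrays scaled near 500 and near 150 (camera adjusted p = 0.00554, and adjusted p = 0.387 with an estimated correlation).

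**Figure D2:**
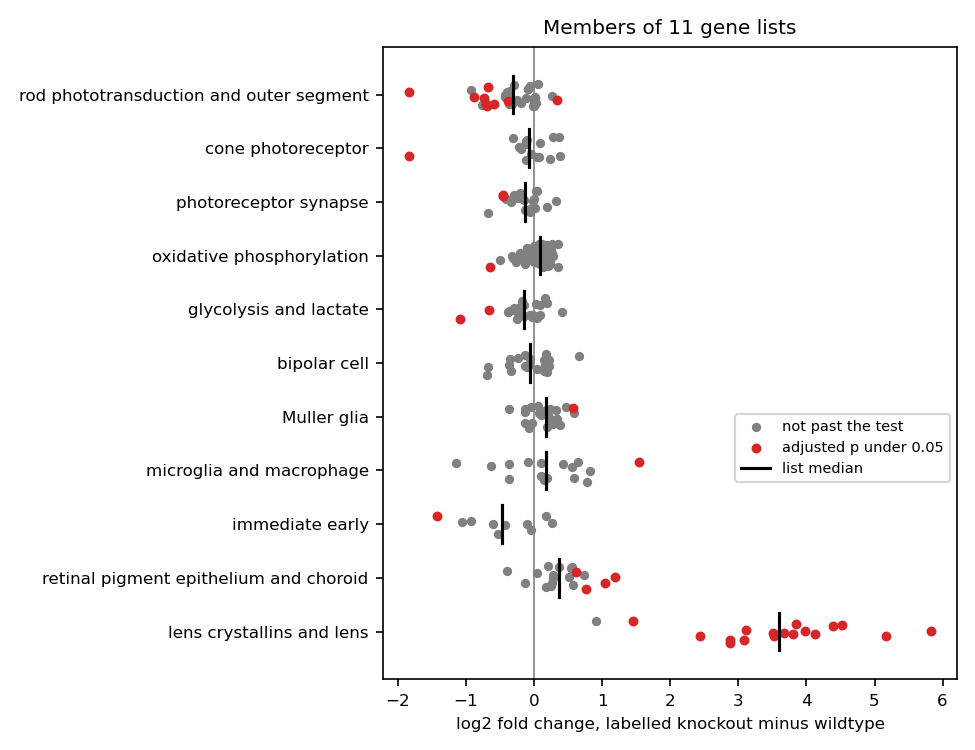
Log2 fold change (x axis, labelled knockout minus wildtype) of each measured member of 11 of the gene lists (y axis), with genes at adjusted p under 0.05 in red, other genes in grey and the list median as a black line. The lens list has its median at 3.60, and the rod list at -0.31 with 8 members lower and 1 higher in red.

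On the glycolysis and lactate list, Hk2, a hexokinase, fell by 1.08 ± 0.071 on the log2 scale (adjusted p = 0.000103; -1.13 and -0.97 in the arrays scaled near 500 and near 150) and the phosphofructokinase gene Pfkp by 0.65 ± 0.13, while the other 20 of 22 measured members did not pass (1 rose and 6 fell when adjusted over the list alone). These 22 include Pigq (0.03, not past the test), matched through a synonym to the list's entry Gpi1. Pigq is not a glycolysis gene, and glucose-6-phosphate isomerase, meant by Gpi1, was not tested on this list. The list passed as lower (median -0.14, adjusted p = 0.0154, and adjusted p = 0.584 with an estimated correlation), but its median was -0.16 in the arrays scaled near 500 and 0.07 in those scaled near 150. Oxidative phosphorylation genes passed as higher on balance (74 measured, median 0.09, adjusted p = 0.024, and adjusted p = 0.569 with an estimated correlation). No member rose, and Ndufs5, a subunit gene of complex I, fell by 0.65 ± 0.12 (1 rose and 1 fell when adjusted over the list alone). Fatty acid oxidation genes also passed as higher (18 measured, median 0.15, adjusted p = 0.024, and adjusted p = 0.387 with an estimated correlation), with no single member past the test; Hadh had 0.34 and Etfb 0.33. Genes of ATP use and ion pumps passed as lower (15 measured, median -0.11, adjusted p = 0.0273, and adjusted p = 0.387 with an estimated correlation), and Slc8a1, a sodium calcium exchanger gene, fell by 0.49 ± 0.10 (1 rose and 4 fell when adjusted over the list alone). The tricarboxylic acid cycle list (22 measured, median 0.06, adjusted p = 0.204) did not pass. Adjusted over the list alone, 2 of its members rose. The list of mitochondrial biogenesis and ERR coregulators did not pass either (20 measured, median 0.01, mean -0.02, adjusted p = 0.662). Its member Nrip1, a corepressor of nuclear receptors, fell by 0.67 ± 0.079 (adjusted p = 0.0038), and Ppargc1a had -0.31 (adjusted p = 0.128). With a replicate block Pfkp, Ndufs5 and Slc8a1 did not pass (adjusted p = 0.0833, 0.072 and 0.102). The values in the arrays scaled near 500 and near 150 were -0.87 and -0.22 for Pfkp and -0.84 and -0.27 for Ndufs5. Within the arrays scaled near 500 and near 150, the medians were 0.11 and 0.03 for oxidative phosphorylation, 0.17 and 0.20 for fatty acid oxidation, and -0.12 and -0.15 for ATP use.

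Markers of the inner retinal neurons did not pass as lists. The medians were -0.06 for 20 bipolar cell genes (adjusted p = 0.588), -0.05 for 16 amacrine cell genes (adjusted p = 0.426), -0.04 for 9 horizontal cell genes (adjusted p = 0.513) and -0.06 for 13 ganglion cell genes (adjusted p = 0.492), and no member passed over all probe sets. Adjusted over each list alone, 1 bipolar cell gene rose and 1 fell, and 1 amacrine cell gene fell. Müller glia genes passed as higher (23 measured, median 0.17, adjusted p = 0.024, and adjusted p = 0.584 with an estimated correlation), with medians of 0.16 and 0.03 in the arrays scaled near 500 and near 150. Of these Rdh10, a retinol dehydrogenase gene, rose by 0.58 ± 0.080 (3 rose when adjusted over the list alone). The glial stress response list did not pass (23 measured, median 0.03, adjusted p = 0.588), though its member S100a6 rose by 0.94 ± 0.20 (3 rose and 1 fell when adjusted over the list alone). On the microglia and macrophage list (16 measured, median 0.17, adjusted p = 0.225) Lgals3, a galectin gene, rose by 1.55 ± 0.29 (2.02 and 0.61 in the arrays scaled near 500 and near 150), while Ly86 and C1qb had 0.64 and -0.37 and did not pass. With a replicate block S100a6 and Lgals3 did not pass (adjusted p = 0.0604 and 0.0679).

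Immediate early genes, which respond to neuronal activity and stress, passed as lower. Among 10 measured, Fos, which lies among the 50 tested genes on one side of Esrrb, fell by 1.42 ± 0.18 on the log2 scale (adjusted p = 0.00577), and Dusp1 (-0.52), Fosl2 (-1.06) and Egr1 (-0.93) did not pass over all probe sets (6 members fell when adjusted over the list alone). The list's median was -0.47, with -0.70 and -0.19 in the arrays scaled near 500 and near 150 (adjusted p = 0.00481, and adjusted p = 0.569 with an estimated correlation). The circadian clock list passed as lower (17 measured, median -0.10, -0.11 and -0.12 in the arrays scaled near 500 and near 150, adjusted p = 0.0355, and adjusted p = 0.387 with an estimated correlation). Its member Per3 fell by 0.52 ± 0.11 (adjusted p = 0.105 with a replicate block), and Per2 and Per1 had -0.88 and -0.44 (2 members fell when adjusted over the list alone).

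Ribosomal protein genes passed as higher (18 measured, median 0.16, 0.16 and 0.18 in the arrays scaled near 500 and near 150, adjusted p = 0.00294, and adjusted p = 0.569 with an estimated correlation) with no single member past the test. On the antioxidant list, which did not pass (18 measured, median 0.03, adjusted p = 0.203), the glutathione enzyme genes Gpx1 (0.51 ± 0.089) and Gsr (0.67 ± 0.14) rose, which they did not with a replicate block (adjusted p = 0.0722 and 0.0818). No member of the lists for cell death (17 measured, median 0.02, mean -0.04, adjusted p = 0.513), unfolded protein response (23 measured, median 0.00, mean -0.03, adjusted p = 0.461), interferon and antigen presentation (14 measured, median -0.14, adjusted p = 0.161) or cholesterol synthesis (16 measured, median -0.05, adjusted p = 0.709) passed, and neither did these lists. Other tissues were represented by the vascular list, on which Acta2, a smooth muscle actin gene, rose by 1.38 ± 0.15 (19 measured, median 0.05, adjusted p = 0.588). Adjusted over the list alone, 1 rose and 2 fell. The lists for cornea (4 measured, median 0.22, adjusted p = 0.516), astrocytes and optic nerve (5 measured, median 0.11, adjusted p = 0.552) and erythrocytes (4 measured, median -0.36, adjusted p = 0.225) did not pass. Of the erythrocyte genes 2 fell when adjusted over the list alone. Lens and pigment cell genes were higher in the same arrays as Acta2, Lgals3 and the Müller glia list, by the medians of 3.60 and 0.37 given above. The lower Actb ratio of the labelled knockout arrays (at most 1.82, against at least 1.83) stands beside every list and gene described here, while the Gapdh ratio did not split by group.

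On the list of genes reported to vary between these strains, Glo1, the glyoxalase gene, rose by 0.90 ± 0.071 (adjusted p = 0.000416). Pttg1 had -2.08 ± 0.78 and did not pass (adjusted p = 0.177), and the list of 7 measured genes did not pass (median 0.03, mean -0.13, adjusted p = 0.662). The Y-linked Eif2s3y fell by 0.79 ± 0.13 (adjusted p = 0.0218, and 0.0604 with a replicate block), and the list of 4 sex-linked genes passed as lower (median -0.45, -0.60 and -0.30 in the arrays scaled near 500 and near 150, adjusted p = 0.0308, and adjusted p = 0.387 with an estimated correlation). Across the 6 arrays the signal of Xist was at least 1169 and that of Eif2s3y at least 188.

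Over 27022 probe sets and 12536 genes, limma with the scaling batch as a block called 609 probe sets (280 higher, 329 lower) and 345 genes (160 higher, 185 lower). At least 2-fold changes were seen in 47 of the genes that rose and 28 of those that fell. All 345 had the same direction in both batches, which their selection by a fit over both favours; of all genes tested, 56.6% did. With a replicate block instead, 200 probe sets and 116 genes passed, 62 higher and 54 lower, all of them among the 345, and 13 lists passed in each of these fits. The fit fixed before the data were examined, which assumed that all 6 arrays were on a single scale, called no probe set or gene (118 probe sets and 40 genes at an unadjusted p under 0.05, and 1426 genes with array weights) and 8 lists. Its smallest p among higher genes, none passing, belonged to Crygb (adjusted p = 0.376), Crygd, Cryba4, Crybb1 and Bfsp1, and among lower genes to Mef2c (adjusted p = 1.0), Traf3ip3, Abca13, Prune2 and Ntng2. Its lists were those of lens, rods, photoreceptor transcription factors, pigment epithelium, immediate early genes, interferon, erythrocytes and sex-linked genes, of which only the lens list passed with an estimated correlation (adjusted p = 0.000363).

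**Figure D3:**
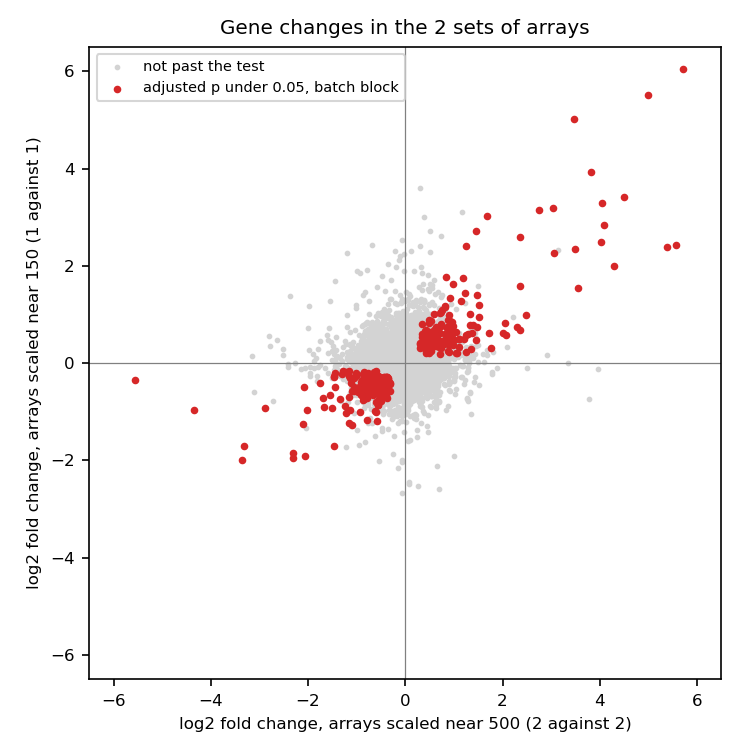
Log2 fold change of each gene tested in the 4 arrays scaled near 500 (x axis) and in the 2 arrays scaled near 150 (y axis), with the genes called with the batch as a block in red and all others in grey. The red points lie on the same side of 0 on both axes, as a fit over both sets of arrays selects for, while over all 12536 genes the correlation across genes, which are not independent replicates, was 0.271.

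The arrays scaled near 500 alone, 2 against 2, called 1830 genes. Of the 1823 that were also tested over all 6 arrays, 68.2% had the same direction in the pair scaled near 150. Without a variance trend the fit with the batch as a block called 13 genes, and leaving out single arrays gave from 46 genes (without wildtype replicate 2) to 1743 (without replicate 3 of either group). Leaving out a replicate 3 array leaves the contrast to the arrays scaled near 500, so that range reflects fold changes as well as their spread.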

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

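The scaling batch as a block, its combination with the other settings and the arrays scaled near 500 alone were chosen after the data were seen; the other settings were planned. The fit without a block called 0 probe sets, 0 genes and 8 lists. This became 609 probe sets, 345 genes and 13 lists with the batch as a block, and 200 probe sets, 116 genes and 13 lists with a replicate block. Quantile normalization gave it 4 probe sets and 2 genes, median centring 3 probe sets, 2 genes and 4 lists, array weights 4194 probe sets and 1426 genes, and the mean of a gene's probe sets 3 genes. Its lists numbered 2 with no filter, 5 with the 60th percentile filter, 1 with an estimated correlation and 1 with fry. Leaving out 1 array gave 0 to 11 probe sets, 0 to 7 genes (2 without wildtype replicate 3, 7 without knockout replicate 3) and 4 to 9 lists. Quantile normalization and median centring put the arrays on a common scale, so scale alone does not account for the few calls without a block.

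With the batch as a block, no filter gave 405 probe sets and 219 genes, the 60th percentile filter 955 and 527, array weights 3891 and 1808, a fold of at least 1.5 363 and 200, the arrays scaled near 500 alone 3710 and 1830, and no block 0 and 0 with 8 lists. Without a variance trend 19 probe sets, 13 genes (10 higher, 3 lower) and 7 lists passed. Lists numbered 0 with an estimated correlation and 3 with fry. Leaving out 1 array gave 79 to 3702 probe sets, 46 to 1743 genes and 7 to 13 lists. Genes numbered 69 without wildtype replicate 1, 46 without wildtype replicate 2, 70 and 68 without knockout replicates 1 and 2, and 1743 without replicate 3 of either group, which leaves the contrast to the arrays scaled near 500. The pair left with 1 array is assumed to vary like the others. The offset, the floor, quantile normalization, median centring, the suffix filter and the mean of a gene's probe sets kept the count of genes within 1.5 times. With the mean of a gene's probe sets 56.9% of called genes were higher, against 46.4%.

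Esrrb kept its direction throughout; its log2 fold change of 0.37 passed with the 60th percentile filter (adjusted p = 0.0393), which tests fewer probe sets. In the filtered fit with the batch as a block (adjusted p = 0.0529) it also passed with the offset (0.0499), the floor (0.0499), the suffix filter (0.0454), the mean of its probe sets (0.0478), array weights (0.0143), the arrays scaled near 500 alone (0.0283) and without replicate 3 of either group (0.0294 and 0.0298). Of 56 genes that passed and are named or listed, 13 still passed without a variance trend, 39 with a replicate block and 45 with no filter. They numbered 33 and 27 without wildtype replicates 1 and 2, and 32 and 34 without knockout replicates 1 and 2. Prune2 turned to 0.62 and Cacna2d4 to 0.010 in the arrays scaled near 500 alone and without wildtype replicate 3, where another probe set represents each gene; leaving out 1 array gave -5.55 to 0.62 for Prune2 and -0.51 to 0.010 for Cacna2d4. Esrrg, near 0, turned to 0.0042 with median centring, 0.084 with array weights, 0.099 with the mean of its probe sets and 0.075 in the arrays scaled near 500 alone, and ranged from -0.075 to 0.075 when single arrays were left out. The cause of the other changes was not tested.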

Other observations

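The tests of crystallin genes alone, of lens RNA, of rod share and of dilution were chosen after the results were seen, as were the genes named next, and the rules that label lens RNA and rod share were rewritten after their values were seen. The test of crystallin genes alone replaced one on the median of all lens genes that are not crystallins, which had not decided. They are called genes outside the fixed lists, with no test of any shared theme. Slc6a6, the taurine transporter gene, changed by -0.92 (adjusted p = 0.00304) and was lower in both batches (-1.10 and -0.57 in the arrays scaled near 500 and near 150). Pfkfb2, which encodes a regulator of phosphofructokinase, changed by -1.16 (adjusted p = 0.000172), in the direction of Hk2 and Pfkp. Sgk1, a glucocorticoid-induced kinase gene, changed by -1.18 (adjusted p = 0.00112), and the negative regulator of inflammation Tnfaip3 by -0.82 (adjusted p = 0.0019). Crb1, an apical polarity gene of photoreceptors and Müller glia, was higher by 1.57 (adjusted p = 0.0149), with 2.06 and 0.57 in the arrays scaled near 500 and near 150. Grifin, a lens galectin, rose by 2.79 (adjusted p = 0.00172), and the connective tissue proteoglycan gene Dcn by 2.13 (adjusted p = 0.00882).

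The rise of lens genes has lens RNA in the samples labelled knockout as a candidate explanation, set against induction in the retina. Crystallin genes alone do not account for it, since 3 of the 4 measured members of the list that are not crystallins (Bfsp1, Mip and Lim2) also passed as higher. In the arrays scaled near 500 the signal of Cryba1 went from 622 to 12086 and that of Crygb from 195 to 10041. A further 7 lens genes outside the list had a median log2 fold change of 0.084 (95% bootstrap interval -0.067 to 0.47), under the bound of 0.5 first set for rejecting lens RNA, which alone would have rejected it, but that bound, set with 1 of them (Prox1, on the horizontal cell list) already seen, assumed a lens profile that no sample here gives, and it was set aside after the value was seen. Their values ran from -0.33 for Prox1 to 2.87 for Gja3 (adjusted p = 0.0558, low wildtype signal of 19.1). In wildtype arrays scaled near 500 Prox1, Maf and Caprin2 already read 976, 652 and 459. Whether added lens RNA would show at such signals is unknown without a lens sample. Cryba1 rose from a like signal of 622. Hsf4 and Epha2 read 83.4 and 116 and had 0.47 and 0.084 without passing. These genes therefore do not decide on lens RNA. Bfsp1, Mip and Lim2, and Grifin outside the list, go with it. Lens RNA and a wider lens programme in the retina cannot be told apart here.

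The lower rod list has a smaller share of rods and dilution by lens or pigment cell RNA as technical candidates beside an effect of genotype. The members did not fall alike (Cochran heterogeneity 452 on 33 degrees of freedom, 383 with a replicate block, and 331 with a replicate block and Cngb1 left out). That test takes genes of the same arrays as independent. Equal falls would be required only if every member were expressed in rods alone, and Guca1a is also on the cone list. Members not on the cone list also differed beyond their errors, such as Slc24a1 (-0.88 ± 0.13) and Pde6b (-0.01 ± 0.068). The spread therefore argues against a smaller share of rods as the only cause. It does not decide whether a smaller share contributed. The rod median lay below that of 58 genes of inner neurons by 0.25 (a difference of -0.25, 95% bootstrap interval -0.40 to -0.0015). The interval resamples genes of the same arrays as if independent. It covers the spread between genes only and does not decide on dilution. The medians of rods and inner neurons were -0.40 and -0.06 in the arrays scaled near 500. In the pair scaled near 150 the medians were -0.01 for rods and -0.06 for inner neurons, so no rod list shift was seen there to explain. Whether rod share or dilution contributed remains open, as do genotype and strain, which are confounded.

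Chromosome segments of Sv129 origin could account for some of the 345 called genes, as could an effect of genotype. Among 100 tested genes flanking Esrrb, 3 were called (Ylpm1, Fos and Dio2, of which only Fos passed with a replicate block), an odds ratio of 1.09 against the other genes (95% interval 0.22 to 3.31, Fisher's exact p = 0.757), too wide to exclude a passenger region. Elsewhere, with the lens list left out, 12 pairs of called genes were neighbours, against 8.57 expected from 10000 random draws (one-sided permutation p = 0.149). Among them were Ppt1 with Cap1, Gsr with Gtf2e2 and, within gene families, Hspa1b with Hspa1a and Guca1b with Guca1a. Some pairs, such as Arid5b with Tmem26 (-0.58 and 2.10), moved in opposite directions. Of 217 genes called in the arrays scaled near 500 alone with at least 2-fold changes, 200 remained after the lens list and genes without a chromosome in the reference gene table were left out, of which 98 had little change in the other pair (under 0.25 of it), and 1 pair of these were neighbours against 0.762 expected (one-sided permutation p = 0.538). No test here decides between strain and genotype.

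The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. With the batch as a block, the real split gave 609 probe sets, 345 genes and 13 lists, and the highest of the other splits gave 6, 1 and 8; 1 of the 10 splits, the real one, gave counts as large. The real split parts all 3 replicate pairs, and the 3 other splits that do so gave at most 1 probe set and no gene. Without a block the real split gave 0 probe sets, 0 genes and 8 lists, and the highest of the others gave 1, 1 and 8, so all 10 splits gave as many probe sets and genes and 2 gave as many lists.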
